A study of Mus musculus with 5 samples.

How the data were processed

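The data are single-cell RNA sequencing libraries of 3T3-L1 cells, 1 library for each of 5 groups: day 0, day 3 without and with P-G3, and day 6 without and with P-G3. The files deposited for each library hold a matrix of UMI counts per gene and cell barcode, with the gene symbols, Ensembl gene identifiers and barcodes in matching order. Reads were aligned to GRCm38 with Cell Ranger 3.1.0 per the submitters' processing notes, whereas the matrix headers name Cell Ranger 5.0.1, so the version is uncertain. The annotation release is not stated. The libraries were made with the 10x Genomics Chromium single cell 3' v2 protocol, per the labels' protocols, but the cell barcodes look like those of the v3 chemistry, so the version is uncertain. The matrices list only barcodes already called as cells, between 3247 and 5719 per library, and no normalization had been applied to the deposited counts. The total per library lay between 92556168 and 179449285 UMIs. No file gives cell types, so these were rebuilt from clusters.

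Barcodes were kept with at least 500 detected genes and at most 20% of UMIs from mitochondrially encoded genes. This kept 98.9% of barcodes on day 0, 97.4% on day 3 untreated, 98.5% on day 3 with P-G3, 46.7% on day 6 untreated and 62.0% on day 6 with P-G3. The kept barcodes on day 6 untreated held 95.5% of that library's UMIs. No doublets were removed. Scrublet as provided in scanpy called 5 of the kept cells doublets, 2 on day 0, 2 on day 3 untreated and 1 on day 3 with P-G3, which is too few for the caller to have worked, so leaving out the 5% of cells with most UMIs was added as an alternative.

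UMIs were summed over the kept cells of each library and expressed as CPM, which scales each gene to the sum of all UMIs in those cells. Ratios are log2((CPM + 1) / (CPM + 1)), which understates differences of genes with low levels. The bound for a gene with no count is 3 counts of the library total. Sums carry exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals. The limits differ by library because of depth, with 3 counts corresponding to 0.0167 CPM in the deepest library and 0.0339 CPM in the shallowest. Genes with at least 20 CPM in either library of a comparison were counted as higher or lower at 2-fold or more. The comparisons were day 3 with day 0, day 6 with day 3 and day 6 with day 0 among untreated libraries, and P-G3 with untreated on day 3 and on day 6. With 1 library per group no comparison has replicates, and no test was made across samples or from cells. A model with day and P-G3 as additive terms would leave 1 residual degree of freedom, and was not fitted.

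The named genes follow a rule. For each comparison they are the 10 highest and the 10 lowest log2 ratios among genes with at least 50 CPM in either library and the same direction under total-count, TMM and median-of-ratios scaling, leaving out mitochondrially encoded genes, ribosomal protein genes and unnamed gene models. To these come the 2 to 4 members of each described list with the largest ratios among those with at least 20 CPM, and 20 anchor genes of adipocyte biology given for every comparison. The comparisons, this rule, 22 alternatives and 56 gene lists were fixed before the data were examined. The lists comprise 35 biological programmes, 8 sets of cell type markers, 7 sets of genes of other cell types, 4 quality sets and 2 cell cycle sets. Each is described by the median log2 ratio of members with at least 5 CPM and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Lists overlap and are not independent. Genes with no count in 1 library were also set to their bound, which left every list median at the value given. Intervals of list medians come from 2000 bootstrap draws over members.

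Transcript lengths and gene positions were taken from GENCODE vM21 (GRCm38), matched on the Ensembl identifier, and 32158 of 32285 genes had a length. It was defined as that of the longest protein-coding transcript, or of the longest transcript of any type where a gene had no protein-coding one. The length trend was found in the data. It was removed, in an alternative chosen after that, by subtracting from each log2 ratio the median of the gene's bin among 20 bins of length.

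Cells of all libraries were clustered together with no batch correction. The 2000 most variable genes, leaving out the lists for fatty acid synthesis, triglyceride synthesis, lipid droplet proteins, S phase and G2/M phase, gave 30 principal components, a graph of 20 nearest neighbours with Jaccard weights and Leiden clusters at resolution 1. A cluster was named after a class when at least 3 of the fixed markers of that class led in it, more than of any other class, and when no other class had more of its markers among the 10 leading genes. This left cluster 6 unnamed, with 1049 of its 1065 cells from day 0, where 10 dividing and 8 preadipocyte markers led but only preadipocyte markers were among the 10 leading genes. Clusters whose cells held fewer UMIs than the median of their own library divided by 3 stayed unnamed, a threshold chosen after seeing the data. Classes were compared within only where both libraries held at least 100 of their cells. For shares of cells with a UMI, each cell was thinned to 1000 UMIs, which left out 1, 9, 8, 90 and 159 cells of the 5 libraries from day 0 to day 6 with P-G3. A dividing cell had at least 2 UMIs over 10 mitotic genes after thinning.

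The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for median-of-ratios size factors. The TMM factors were 1.01, 1.09, 0.922, 1.12 and 0.884 from day 0 to day 6 with P-G3. Neither package was used for a test.

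The calculations were tested on simulated counts for the comparison of P-G3 with untreated on day 6. The counts were Poisson draws from the pooled mean of the 2 libraries, with no variation between libraries. The results therefore check the calculations only, and do not show how far replicate libraries would differ. All of 100 genes changed 3-fold were called at 2-fold, none of 100 genes changed 1.5-fold was, and 0 of 4867 unchanged genes were called. The ratio intervals held the true ratio for 95.2% of 5067 genes. Of lists without a change, 6.5% fell outside the central 95%, and 100% of lists raised by 0.5 lay above it, over 8832 genes. A length trend put in at a Spearman correlation of -0.54 came out at -0.01 after removal over 8827 genes, and a list of 100 genes lowered by 1 kept a median of -0.90. In simulated cells of 3 kinds with 300 cells each, drawn from the mean profiles of the untreated libraries, 100% fell into a cluster led by their own kind. This score does not fall when 1 kind is split over several clusters.

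The alternatives were TMM and median-of-ratios scaling, a pseudocount of 5 CPM, other minimum levels and folds, all deposited barcodes, a stricter cell filter, doublet calls left out, equal weight for each cell, other clustering resolutions, clustering on all variable genes or on thinned cells, other thinning depths and UMI minimums, and Adipoq UMIs in place of clusters. A further 5 were added after seeing the data: removal of the length trend, a minimum of 10000 UMIs per cell, leaving out the 5% of cells with most UMIs, the naming threshold for low-UMI clusters, and each adipocyte-like cluster alone. Reads were not used here, so alignment, UMI counting and cell calling rest on what the authors ran.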

Results

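Single-cell transcriptomes were measured in 3T3-L1 cells, a mouse fibroblast line committed to the adipocyte lineage. Confluent cells were induced to differentiate with dexamethasone, insulin and isobutylmethylxanthine and were then kept in insulin. Cells were collected on days 0, 3 and 6, and on days 3 and 6 also from cultures that had received 10 µg/mL of P-G3, a PAMAM polymer with many positive charges, from the start of induction. There was 1 library in each of the 5 groups, so no difference given here has a replicate check, and no test between groups was made. Intervals of levels, ratios and shares cover counting error only, and those of list medians cover the spread over list members only. The kept cells numbered 3210 on day 0, 3596 on day 3 untreated, 3893 on day 3 with P-G3, 2468 on day 6 untreated and 3546 on day 6 with P-G3. They held 158720026, 139767386, 179221992, 88432894 and 107429490 UMIs in the same order.

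The day 6 libraries held many barcodes with few molecules. The median number of UMIs per kept cell was 47504 on day 0, 34720 on day 3 untreated, 40306 on day 3 with P-G3, 34214 on day 6 untreated and 16658 on day 6 with P-G3. Kept cells under 10000 UMIs made up 0.872% of the day 0 library, at most 5.65% of each day 3 library, and 37.6% and 47.0% of the day 6 libraries. These cells held only 2.58% and 4.05% of the kept UMIs on day 6 without and with P-G3, so sums over a library rest almost wholly on the larger cells. The median share of UMIs from mitochondrially encoded genes was 3.37% on day 0 and between 4.75% and 6.29% in the other libraries.

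**Figure D1:**
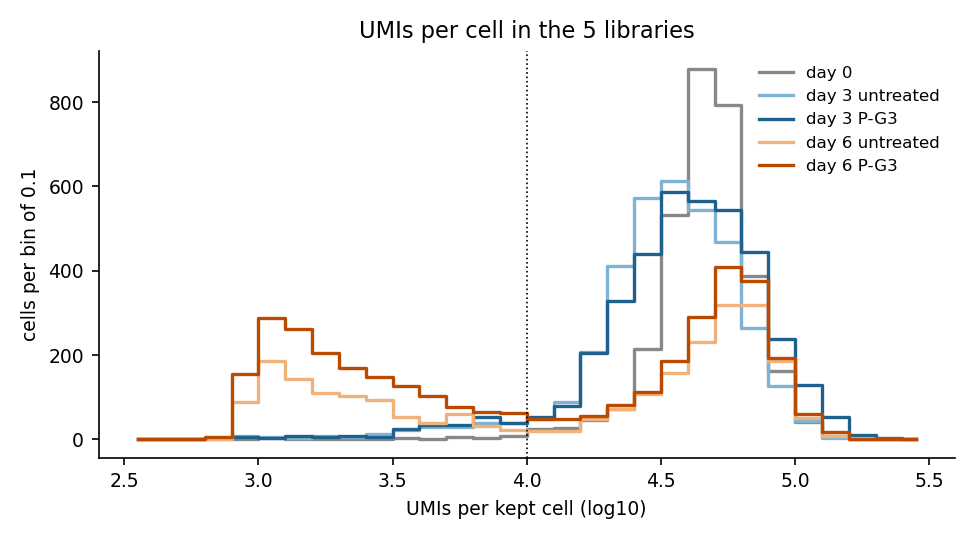
Number of kept cells (y axis, cells per bin of 0.1) against UMIs per cell (x axis, log10 scale) in the 5 libraries, with a dotted line at 10000 UMIs. On day 6 a separate group of small barcodes lies left of the line, with 37.6% of kept cells untreated and 47.0% with P-G3.

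The first comparison asks which genes differ when preadipocytes enter adipogenesis, by setting day 3 untreated against day 0. Adipocyte genes were higher on day 3, and genes of contractile, chemokine-secreting fibroblasts were lower. Fabp4, the fatty acid carrier of adipocytes (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576, GRCm38), stood at 30.4 CPM on day 0 and 6964 CPM on day 3, a log2 ratio of 7.79. G0s2, an inhibitor of triglyceride breakdown, went from 0.485 to 410 CPM (8.11), and Retn, which encodes resistin, from 0.0819 to 152 CPM (7.15). The transcription factors that drive adipogenesis were higher as well, with Pparg at 14.4 and 82.1 CPM (2.44) and Cebpa at 1.53 and 29.2 CPM (3.58). All 19 measured adipocyte identity markers were higher, with a median log2 ratio of 4.39, the percentile being 100 among 10000 random lists matched on expression. Adipoq, the gene of adiponectin, and Cidec, a lipid droplet protein, each had 1 UMI on day 0 against 32.6 and 90.7 CPM on day 3, and the 95% intervals of their log2 CPM ratios were 9.86 to 17.64 and 11.34 to 19.12. Plin1, which coats lipid droplets, had 3 UMIs on day 0 and 35.1 CPM on day 3, with an interval of 9.31 to 13.14.

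The other highest genes of this comparison were the lipocalin Lcn2 (6.13), the fatty acid transporter Cd36 (5.77), Wfdc21 (5.73), Agt, which encodes angiotensinogen (5.71), Aldh1a7 (5.70) and Orm1 (5.20). Glucocorticoid targets, read here because the cocktail contains dexamethasone, were higher in 18 of 19 members with a median of 2.13, led by Lcn2, Zbtb16 (4.80) and Glul (4.57). Lipolysis genes were higher in 11 of 11 members (2.14), triglyceride synthesis genes in 13 of 16 (1.42), with Acsl1 at 4.90 and Dgat2 at 3.87, and fatty acid synthesis genes in 14 of 19 (0.60), with Scd1 at 2.11 and Fasn at 1.27. Nuclear genes of mitochondrial respiration were higher in 51 of 53 members (0.42) and tricarboxylic acid cycle genes in 23 of 23 (0.71), led by pyruvate carboxylase, Pcx (4.81). Basement membrane genes were higher in 15 of 15 members (0.98).

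The lowest gene was Spp1, which encodes osteopontin, at 1200 CPM on day 0 and 39.8 CPM on day 3 (-4.88). The metalloproteinase inhibitors Timp1 (2194 to 167 CPM, -3.71) and Timp3 (-3.27), the muscle genes Tagln (-3.65), Myl9 (-2.98) and Tnnt2 (-3.51), the chemokines Ccl2 (259 to 20.9 CPM, -3.57) and Ccl7 (-3.53), Ccn5 (-3.56) and Prkg2 (-2.98) completed the lowest 10. Targets of the actin-regulated factors SRF and YAP were lower in 20 of 21 members (-1.18), TGF-beta targets in 13 of 19 (-0.77) and inflammation genes in 13 of 17. The preadipocyte marker Dlk1 went from 2125 to 547 CPM (-1.96) and Col1a1, which encodes collagen I, from 1146 to 468 CPM (-1.29). ATF4 targets were lower in 21 of 25 members (-0.76) and cholesterol synthesis genes in 16 of 22 (-0.31). All 44 S phase genes were lower (-0.47), whereas G2/M genes were split 34 higher and 19 lower (0.12, and -0.03 under median-of-ratios scaling), with Mki67 at 0.47 and Top2a at 0.02 (-0.09 under TMM scaling).

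Of 5716 genes with at least 20 CPM in either library, 348 were at least 2-fold higher and 217 at least 2-fold lower on day 3. The split was 287 and 269 under TMM scaling and 267 and 303 under median-of-ratios scaling, which moved the median log2 ratio of all genes from 0.02 to -0.09 and -0.13. Of 45 lists with at least 3 measured members, 29 lay outside the central 95% of random lists, 18 above and 11 below.

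From day 3 to day 6 the question was which genes accompany maturation. Lipid-storing and secretory genes of adipocytes were higher on day 6 and cell division genes were lower. Scd1, the desaturase that makes monounsaturated fatty acids (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), stood at 121 CPM on day 3 and 3210 CPM on day 6 (4.72). Cfd, which encodes adipsin, stood at 46.9 and 902 CPM (4.24), and Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) at 32.6 and 459 CPM (3.78). The insulin-regulated glucose transporter gene Slc2a4 stood at 2.73 and 44.7 CPM (3.62). The gene with the highest ratio was Ghrh, known as the hypothalamic growth hormone-releasing hormone, at 0.594 and 449 CPM (8.14). All 20 adipocyte identity markers and all 20 fatty acid synthesis genes measured were higher on day 6, with medians of 2.26 and 1.16.

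Apoc1 (4.49), the oxidoreductase Ero1l (44.5 to 930 CPM, 4.36), Cdsn (4.27), the melanocortin receptor accessory gene Mrap (3.84), Adig (3.72) and the pseudokinase Trib3 (7.33 to 98.3 CPM, 3.57) were also among the highest 10. Triglyceride synthesis genes were higher in 14 of 16 members (1.46), led by Gpd1 (3.23), and cholesterol synthesis genes in 21 of 22 (1.15), led by Insig1 (2.43) and Sqle (1.88). ATF4 targets were higher in 28 of 28 members (1.40), with Ddit3 at 3.19, and hypoxia targets in 18 of 19 (1.39), with Vegfa at 2.50. Glycolysis genes were higher in 18 of 19 members (0.90), with Hk2 at 2.16. Respiration genes of the nucleus were higher in 51 of 53 (0.44). Glucocorticoid targets were split 10 and 10 (-0.10), with Klf15 at 3.65 and Tsc22d3 at -1.58.

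All 53 G2/M genes were lower on day 6, with a median of -2.04. The spindle genes Nusap1 (98.6 to 8.20 CPM, -3.44), Cenpf (-3.27) and Prc1 (-2.84), the ubiquitin-conjugating enzyme gene Ube2c (270 to 36.1 CPM, -2.87), Mki67 (89.2 to 11.6 CPM, -2.84), Pclaf (-2.81), Birc5 (-2.70) and Stmn1 (-2.66) were among the lowest 10, together with the fibroblast transcripts Dnm3os (-2.80) and Osr1 (-2.65). S phase genes were lower in 42 of 44 members (-1.37). Ribosomal protein genes were lower in 72 of 78 (-0.47). Progenitor markers were lower in 17 of 21 members (-0.68) and matrix genes in 21 of 29 (-0.34), although Col1a1 stood at 468 and 506 CPM (0.11). Of 5936 genes, 464 were at least 2-fold higher and 300 at least 2-fold lower, and 30 of 45 lists lay outside the central 95%, 20 above and 10 below.

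Set against day 0, the day 6 untreated library showed the whole course of differentiation. Adipocyte identity markers were higher in 20 of 20 members with a median of 6.70. G0s2 (10.39), Retn (10.14), Fabp4 (9.51, 22929 CPM on day 6) and Wfdc21 (7.95) were among the highest. Cfd, Ghrh and Mrap had no UMI on day 0, where the limit of 3 counts is 0.0189 CPM, so they were at least 47716-fold, 23780-fold and 20544-fold higher on day 6. Cidec, Adig and Adipoq each had 1 UMI on day 0, and the intervals of their log2 CPM ratios were 14.06 to 21.84, 13.75 to 21.53 and 13.68 to 21.46. Lpl, the lipase that releases fatty acids from lipoproteins, was higher by 5.53, Dgat2, the last enzyme of triglyceride synthesis, by 6.46, Scd1 by 6.83 and Pnpla2, which encodes adipose triglyceride lipase, by 5.10. Nampt, the rate-limiting enzyme of NAD salvage, was higher by 3.28. Leptin, Lep, remained rare at 0.577 CPM on day 6, with UMIs in only 5 of 2468 cells.

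Hmga2, a chromatin gene of growing cells, went from 712 to 22.8 CPM (-4.91). Tnnt2 (-5.28), Ccn5 (-5.18), Timp1 (-5.13), Tagln (-5.06), the BMP antagonist Grem1 (-4.84), Ccl7 (-4.84), Ccl2 (-4.55), Myl9 (-4.34) and Timp3 (-4.30) were the other lowest genes. SRF and YAP targets were lower in 19 of 21 members (-2.05), G2/M genes in 51 of 52 (-1.90), S phase genes in 44 of 44 (-1.88) and matrix genes in 23 of 31 (-0.98). Thermogenic genes were higher in 6 of 7 measured members (1.91), with Cox7a1 at 4.79, although 14 of the 21 listed did not reach 5 CPM. Of 6086 genes, 1011 were at least 2-fold higher and 611 at least 2-fold lower. The split was 820 and 743 under TMM scaling and 810 and 753 under median-of-ratios scaling, with the median of all genes moving from 0.11 to -0.04 and -0.05. Of 45 lists, 36 lay outside the central 95%.

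**Figure D2:**
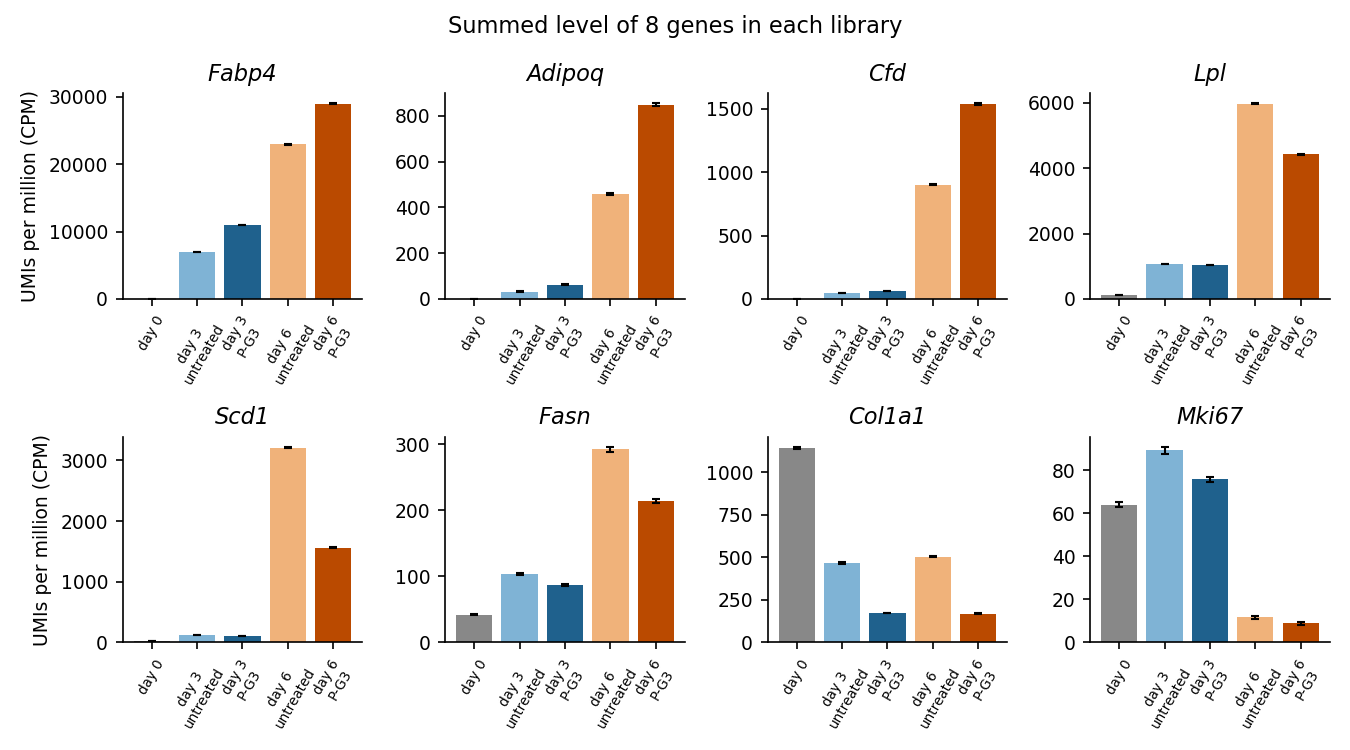
Levels of Fabp4, Adipoq, Cfd, Lpl, Scd1, Fasn, Col1a1 and Mki67 (y axes, CPM over all kept cells) in the 5 libraries, 1 bar per library with exact Poisson 95% intervals. Adipoq stands at 459 CPM on day 6 untreated and 849 CPM with P-G3, Scd1 at 3210 and 1561 CPM, and Col1a1 at 506 and 168 CPM.

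Clustering of the kept cells of all libraries gave 14 clusters, of which 3 were adipocyte-like, 3 preadipocyte-like and 2 dividing cell-like by the fixed markers, 2 stayed unnamed and 4 stayed unnamed with low UMI counts. No adipocyte-like cell was found among 3210 on day 0 (exact upper limit 0.115%). Their share was 9.37% on day 3 untreated (exact 95% interval 8.44% to 10.4%), 10.8% with P-G3 (9.83% to 11.8%), 39.1% on day 6 untreated (37.2% to 41.1%) and 41.2% with P-G3 (39.6% to 42.9%). The threshold that leaves low-UMI clusters unnamed was chosen after seeing the data, and these clusters held 1.34%, 3.03%, 6.45%, 38.2% and 46.9% of cells in the order of the libraries. Among cells with at least 10000 UMIs, clustered again, the adipocyte-like share was 64.0% on day 6 untreated and 79.1% with P-G3. The direction turned on day 6 without the doublet calls (37.8% and 36.3%) and with cells thinned before clustering (43.3% and 42.9%). It also turned on day 3 at the lower resolution (0.250% and 0.128%), which rests on 9 and 5 cells. As a share of all clustered cells, low-UMI clusters included, adipocyte-like cells thus gave no stable difference between treatments. On day 6 the low-UMI clusters held 38.5% and 47.1% without the doublet calls, and 28.5% and 37.2% with thinned cells. No day 6 cell was called a doublet, so the turn without the doublet calls came from clustering anew. Preadipocyte-like cells were 42.5% and 21.8% on day 3 without and with P-G3, but the share with P-G3 ran from 3.40% (cells with at least 10000 UMIs) to 42.7% (cells thinned before clustering) under the alternatives, and the untreated share from 35.5% to 55.8%. On day 6 they were 20.2% and 10.7%, with 31.8% and 18.6% at 10000 UMIs or more. On both days the share was lower with P-G3 under every alternative. Every alternative used the same naming markers, among them Col1a1, Lox and Tagln, which were themselves lower with P-G3. The share can therefore fall without fewer cells of this kind. Unnamed clusters held 15.7% and 28.7% of cells on day 3 without and with P-G3, and 16.7% and 50.2% at 10000 UMIs or more. Most clusters drew their cells from 1 day or 1 treatment. The shares therefore describe these libraries only.

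**Figure D3:**
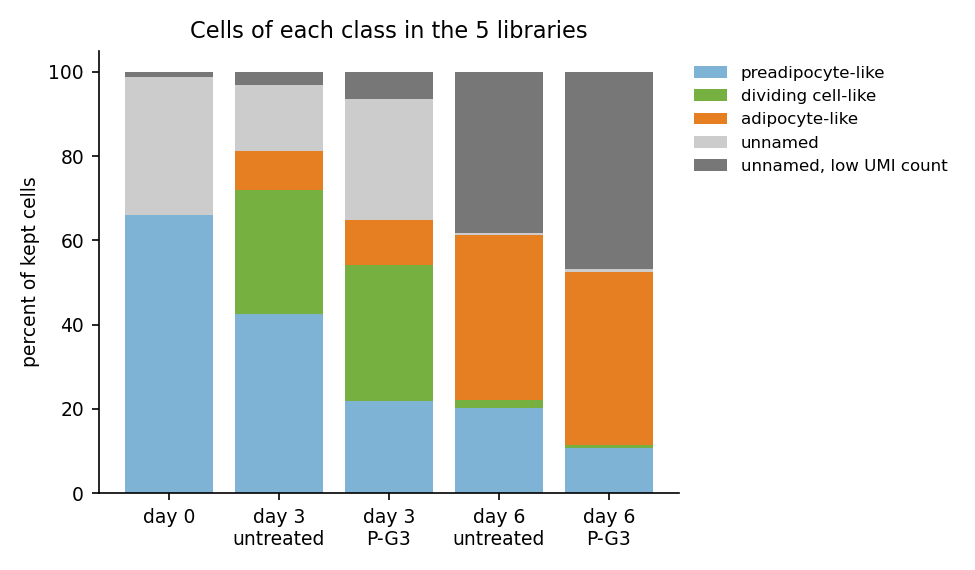
Stacked bars of the share of kept cells (y axis, percent) in each cluster class for the 5 libraries. The adipocyte-like part covers 0% on day 0, 9.37% and 10.8% on day 3 and 39.1% and 41.2% on day 6 without and with P-G3, beside low-UMI clusters with 38.2% and 46.9% on day 6.

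After thinning each cell to 1000 UMIs, the share of cells with a UMI of an adipocyte gene followed the levels. Adipoq was found in 0 of 3209 cells on day 0 at this depth, in 2.01% and 3.47% of cells on day 3 without and with P-G3, and in 27.9% (95% interval 26.1% to 29.7%) and 34.1% (32.5% to 35.7%) on day 6. Without thinning the shares were 0.0312%, 19.1%, 29.6%, 62.0% and 64.5%. In preadipocyte-like cells, which should lack adiponectin, the thinned share on day 6 was 1.40% of 499 untreated cells (median 37524 UMIs) and 1.05% of 380 cells with P-G3 (28660 UMIs), against 42.0% and 51.6% of adipocyte-like cells (62755 and 59170 UMIs). Fabp4 went from 3.05% of cells on day 0 to 96.6% and 98.5% on day 6 (44.2%, 99.9% and 99.9% without thinning), but 86.8% and 92.4% of preadipocyte-like cells held it on day 6, so its share does not mark adipocytes there. Scd1 was found in 2.68% of cells on day 0, and in 55.3% untreated and 45.7% with P-G3 on day 6 (88.3% and 78.8% without thinning), against 15.6% and 13.4% of preadipocyte-like cells. Dividing cells made up 19.4% on day 0, 21.4% and 23.4% on day 3 without and with P-G3, and 2.35% and 2.13% on day 6. Without thinning these were 86.5%, 78.6%, 83.5%, 41.2% and 35.0%.

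Beside every difference between the P-G3 and untreated libraries stood a trend with transcript length. Across genes with at least 5 CPM, which are not independent replicates, the Spearman correlation of the log2 ratio with the length of the longest transcript was -0.60 on day 3 (9210 genes) and -0.62 on day 6 (9132 genes). The median log2 ratio was 0.12 in the bin of shortest genes (743 nt) and -0.58 in the bin of longest genes (9966 nt) on day 3, and 0.16 (737 nt) and -0.72 (10019 nt) on day 6. The differentiation comparisons had correlations of 0.16, -0.02 and 0.08. Values with the trend removed, by subtracting the median of the gene's length bin, are therefore given beside many of the measured ones. Total-count scaling also put the median of all genes at -0.14 on day 3 and -0.25 on day 6, which TMM scaling moved to 0.09 and 0.08 and median-of-ratios scaling to 0.12 and 0.13.

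**Figure D4:**
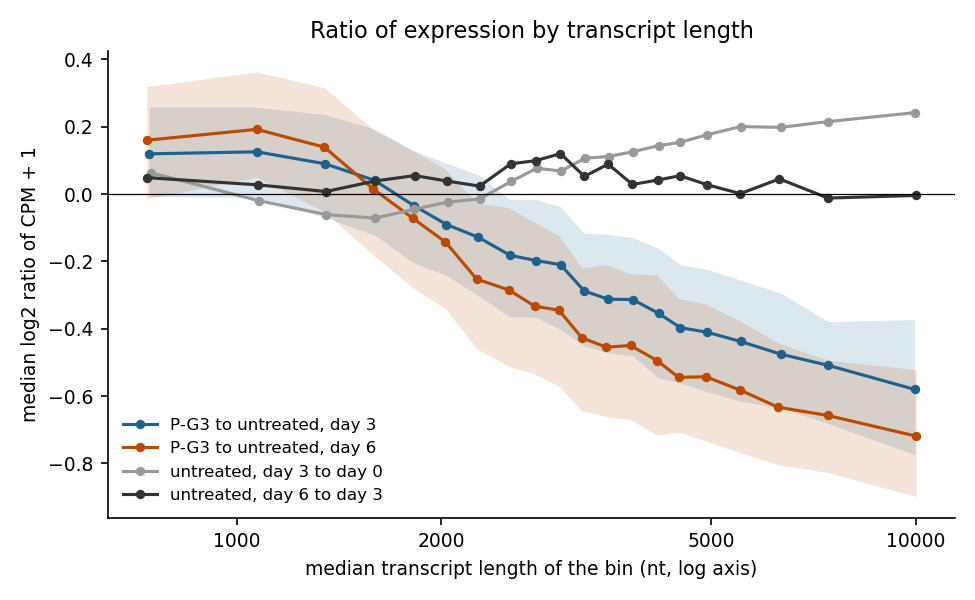
Median log2 ratio of CPM (y axis) in 20 bins of transcript length (x axis, nt, log scale) for P-G3 against untreated on day 3 and day 6, and for untreated day 3 against day 0 and day 6 against day 3. Shaded bands run from the lower to the upper quartile for the P-G3 comparisons. The P-G3 lines run from 0.12 to -0.58 on day 3 and from 0.16 to -0.72 on day 6.

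The comparison of P-G3 with untreated cells on day 3 asks how the polymer alters early adipogenesis. Over all cells, adipocyte markers and glycolysis genes were higher with P-G3, and matrix, fibroblast and cytoskeletal genes were lower. Adipoq stood at 32.6 CPM untreated and 63.0 CPM with P-G3 (0.93, and 0.84 with the length trend removed), Fabp4 at 6964 and 10918 CPM (0.65, 0.53), G0s2 at 410 and 880 CPM (1.10) and Retn at 152 and 283 CPM (0.89). Pparg was higher by 0.44 and Cebpa differed by -0.01. Adipocyte identity markers were higher in 14 of 19 members with a median of 0.37 (percentile 100), which was 0.41 with the length trend removed. Among cells with 30000 to 60000 UMIs it was only 0.03 (0.17 with the trend removed), and by class it was 0.47 in dividing cell-like, 0.06 in adipocyte-like, -0.02 in preadipocyte-like, -0.36 in unnamed and -0.16 in low-UMI clusters. Glycolysis genes were higher in 16 of 17 members (0.47), with the enolase gene Eno1 at 0.92, Tpi1 at 0.88, the lactate dehydrogenase gene Ldha at 0.85 (805 and 1456 CPM) and Gapdh at 0.81. Several of these enzymes have near-identical pseudogenes, so their counts are uncertain to the extent that the counting split reads between copies.

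Hypoxia targets were higher in 13 of 15 members (0.38), led by Ankrd37 (1.27), the mTORC1 inhibitor Ddit4 (0.86) and Bnip3 (0.83). Cholesterol synthesis genes were higher in 18 of 22 (0.20), with the farnesyl diphosphate synthase gene Fdps at 133 and 259 CPM (0.96), and nuclear respiration genes in 51 of 53 (0.22). The cytokine gene Mif had the highest ratio among genes with at least 50 CPM (416 and 900 CPM, 1.11), and Grhpr stood at 0.87. Fatty acid synthesis genes gave no stable direction. They were lower in 14 of 19 members with a median of -0.13 inside the central 95% (percentile 67.2), but the median was 0.11 under TMM scaling and 0.18 with the length trend removed, where it lay above the central 95%. Fasn stood at -0.25 and 0.33 before and after that removal, Scd1 at -0.13 and 0.28, and Acaca at -0.46 and 0.12. Triglyceride synthesis genes had a median of -0.02, which became 0.20 under TMM scaling and 0.27 with the length trend removed.

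Lox, the enzyme that crosslinks collagen (ENSMUSG00000024529, chromosome 18, 52516067 to 52529867), was the lowest gene on day 3 at 201 CPM untreated and 49.8 CPM with P-G3 (-1.99, and -1.58 with the trend removed). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) stood at 468 and 174 CPM (-1.42, and -0.95 with the trend removed). Extracellular matrix genes were lower in 26 of 28 members with a median of -0.73, below every random list, and -0.53 with the trend removed. The median was -0.49 under TMM scaling and -0.46 under median-of-ratios scaling. By class, with the trend removed, the matrix median was 0.02 in adipocyte-like, 0.02 in preadipocyte-like and 0.004 in unnamed clusters. It was -0.61 in dividing cell-like and -0.74 in low-UMI clusters. Of the dividing cell-like clusters, cluster 5 stood at -0.38 and cluster 7 at 0.09. The lower median with the trend removed was thus not seen in every class. SRF and YAP targets were lower in 19 of 20 members (-0.77), with Tagln at -1.97, TGF-beta targets in 13 of 17 (-0.75), progenitor markers in 18 of 21 (-0.72) and inflammation genes in 12 of 13 (-0.70), with Ccl2 at -1.82. Within adipocyte-like cells, with the trend removed, the medians of these lists were -0.004, -0.08, -0.10 and -0.27 in the same order. Only that of the inflammation genes lay below the central 95% there. The atypical GTPase gene Rhou (-1.93), the cadherin gene Cdh11 (-1.83), the growth arrest gene Gas6 (227 and 69.7 CPM, -1.69), Egr1 (-1.57), Adamts1 (-1.56), Pcdh19 (-1.49), Hmga2 (-1.44) and Myh9 (-1.41) were the other lowest genes. Insulin signalling genes were lower in 16 of 20 members (-0.46, percentile 0.64), but their median was 0.03 with the trend removed.

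Of 5439 genes, 7 were at least 2-fold higher and 117 at least 2-fold lower with P-G3 on day 3, a split that became 26 and 41 under TMM scaling, 27 and 35 under median-of-ratios scaling and 9 and 30 with the length trend removed. In both the measured and the length-adjusted ratios 4 genes were higher and 27 lower. Of 45 lists, 23 lay outside the central 95%, 10 above and 13 below, and 20 of them lay on the same side with the trend removed.

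On day 6 the same comparison sums all kept cells, of which 39.1% untreated and 41.2% with P-G3 were adipocyte-like. Cells with at least 10000 UMIs held almost all the summed UMIs, and their mix was less alike. Clustered again, they were 64.0% adipocyte-like untreated and 79.1% with P-G3, and 31.8% and 18.6% preadipocyte-like. Differences between the sums therefore include this difference in mix. Adiponectin and adipsin transcripts were higher with P-G3 while Scd1, matrix genes and immediate early genes were lower. Adipoq stood at 459 CPM untreated and 849 CPM with P-G3 (0.88, and 0.74 with the length trend removed), and Cfd was higher by 0.77. In the largest low-UMI cluster Adipoq went the other way, at 539 CPM untreated and 394 CPM with P-G3. Scd1 stood at 3210 and 1561 CPM (-1.04), and remained lower at -0.70 under TMM scaling and -0.50 with the trend removed. Fabp4 stood at 22929 and 28993 CPM (0.34), Pparg at 0.20, Plin1 at -0.03 (0.30 under TMM scaling) and Pnpla2 at 0.00. Lep had no UMI with P-G3, and its 0.577 CPM untreated came from 5 cells, too few for a comparison. The identity markers as a list were split 8 higher and 12 lower with a median of -0.11 (percentile 5.07), which was 0.22 under TMM scaling, 0.27 under median-of-ratios scaling and 0.08 with the trend removed, so they showed no stable direction.

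The carbonyl reductase genes Cbr1 (206 and 512 CPM, 1.31, and 1.17 with the trend removed) and Cbr2 (1.15) had the highest ratios, followed by Fcf1 (1.07), Selenbp1 (1.07), the stem cell antigen gene Ly6a (1.05), Hsd11b1, which reactivates glucocorticoid (0.98), Mdh1 (626 and 1216 CPM, 0.96), Fdps (0.93) and Psma6 (0.89). Nuclear respiration genes were higher in 48 of 53 members (0.31, percentile 100, but 0.22 with the trend removed, inside the central 95%), with Cyc1 at 0.87, whereas mitochondrially encoded transcripts were lower in 13 of 13 (-0.37, percentile 0.04, and -0.56 with the trend removed, but 0.01 under median-of-ratios scaling). Glycolysis genes were split 11 and 8 (0.05) and tricarboxylic acid cycle genes 13 and 10 (0.09), but with the trend removed their medians were 0.32 and 0.34, above the central 95%.

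Fatty acid synthesis genes were lower in 16 of 20 members on day 6 with a median of -0.30 inside the central 95% (percentile 15.1). The median was 0.03 under TMM scaling and 0.08 with the trend removed, so the direction of the list depends on both. Acaca stood at 53.6 and 30.2 CPM (-0.80, and -0.09 with the trend removed) and Fasn at 292 and 214 CPM (-0.45, 0.27). Triglyceride synthesis genes had a median of -0.34 (percentile 19.8) and 0.13 with the trend removed. Fatty acid uptake genes were lower in 10 of 13 members (-0.36, percentile 1.41), but 0.07 with the trend removed, and Lpl at -0.43 moved to 0.06. Insulin signalling genes were lower in 20 of 21 members (-0.60, percentile 0.25), with a median of 0.03 after removal of the trend.

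All 29 matrix genes measured on day 6 were lower with P-G3, with a median of -0.99, below every random list. The median was -0.66 under TMM scaling, -0.61 for median-of-ratios scaling over the same members (-0.64 with members chosen anew after scaling) and -0.41 with the trend removed. By class, with the trend removed, it was 0.02 in adipocyte-like, -0.12 in preadipocyte-like and -0.77 in low-UMI clusters. Col1a1 stood at 506 and 168 CPM (-1.58, -0.95), Lox at 66.0 and 16.0 CPM (-1.98) and Fstl1 at -1.82. The immediate early gene Egr1 had the lowest ratio (127 and 28.9 CPM, -2.10) and the immediate early list, a quality set because its genes respond to cell handling, was lower in 14 of 17 members (-0.85, and -0.43 with the trend removed, below the central 95% both ways), with Junb at -1.51. Gas6 (-2.07), Gas1 (-1.94), Sox4 (-1.59), Slc5a3 (-1.55), Zfp36l2 (-1.54) and the heparin-binding growth factor gene Ptn (384 and 132 CPM, -1.53) were the other lowest genes. Endoplasmic reticulum folding genes were lower in 22 of 22 members (-0.51, and -0.09 with the trend removed) and inflammation genes in 11 of 12 (-0.73, -0.45), with Cxcl12 at -1.46. Dlk1 differed by -0.41, but by 0.14 with the trend removed.

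Of 5564 genes on day 6, 7 were at least 2-fold higher and 191 at least 2-fold lower with P-G3. The split was 56 and 37 under TMM scaling, 81 and 32 under median-of-ratios scaling and 26 and 28 with the length trend removed, and 4 genes were higher and 25 lower both as measured and with the trend removed. Of 47 lists, 21 lay outside the central 95%, 7 above and 14 below, and 13 of them lay on the same side with the trend removed.

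**Figure D5:**
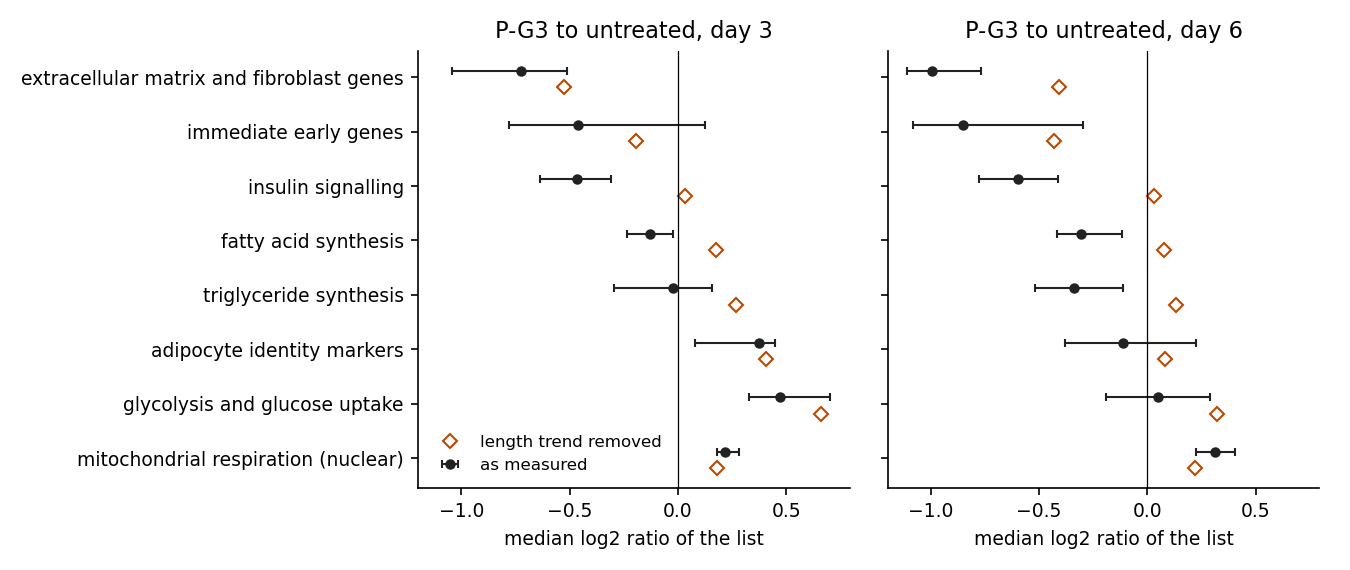
Median log2 ratio of P-G3 to untreated (x axis) for 8 gene lists (y axis) on day 3 and day 6, with black bars for bootstrap 95% intervals over the members and diamonds for medians with the length trend removed. Extracellular matrix genes lie at -0.73 and -0.99, and insulin signalling genes at -0.46 and -0.60 move to 0.03 on both days once the trend is removed.

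Among polyamine, endocytosis, lysosome and NAD genes, only the endocytosis list lay below the central 95% on both days, when the median of all genes was itself -0.14 and -0.25. Polyamine metabolism genes were lower in 13 of 18 members on day 3 (-0.13) and 11 of 18 on day 6 (-0.32), both inside the central 95%, and the medians were 0.08 and 0.01 under TMM scaling. Endocytosis and heparan sulfate genes were lower in 24 of 28 members on day 3 (-0.41) and 26 of 29 on day 6 (-0.53), with Lrp1 at -0.99 and -0.97, and were -0.11 on both days with the trend removed, still below the central 95%. Lysosome genes were lower in 31 of 34 members on day 3 (-0.35, percentile 0.36, and -0.16 with the trend removed) and 30 of 34 on day 6 (-0.37, percentile 12.9, but 0.01 under median-of-ratios scaling). NAD synthesis genes were lower in 13 of 17 members on day 3 (-0.16) and 14 of 16 on day 6 (-0.17), inside the central 95% on both days and at 0.08 and 0.15 under TMM scaling, with Nampt at -0.16 and -0.38.

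Within adipocyte-like cells, 337 untreated and 420 with P-G3 on day 3 and 966 and 1462 on day 6, Adipoq was again higher with P-G3, by 0.63 and 0.69, and Scd1 was lower on day 6 (4391 and 1813 CPM, -1.28, and -0.73 with the trend removed). These cells came mostly from cluster 9 on day 3 and from clusters 3 and 10 on day 6, in proportions that differed between treatments: cluster 3 held 753 untreated and 979 P-G3 cells and cluster 10 held 199 and 478. Scd1 was -1.12 in cluster 3 (-0.63 with the trend removed) and -0.81 in cluster 10 (-0.20), so part of the difference over the class is one between clusters. Adipoq was 0.87 and 0.40 in these clusters. Adipocyte identity markers were split 11 and 9 on day 3 (0.06, percentile 87.3), and were lower in 14 of 21 members on day 6 (-0.41, percentile 0.03, and -0.15 with the trend removed, below the central 95% both ways, but -0.08 under TMM scaling). Within clusters 3 and 10 alone they were -0.26 and -0.22, and with the trend removed -0.03 and -0.02, inside the central 95%. Cebpa stood at -0.40 on day 3 and -0.55 on day 6. Fatty acid synthesis genes were lower in 15 of 20 members on day 3 (-0.27) and 17 of 21 on day 6 (-0.40), but their medians were 0.00 and 0.01 with the trend removed. Matrix genes were lower in 18 of 24 and 23 of 25 members (-0.32 and -0.46), and 0.02 on both days with the trend removed. Glycolysis genes were higher in 17 of 19 members on day 3 (0.38) and had a median of -0.02 on day 6, but 0.32 with the trend removed, above the central 95%. The quality sets differed too on day 6, with mitochondrially encoded transcripts lower in 13 of 13 members (-0.45), immediate early genes lower in 12 of 16 (-0.76, and -0.42 with the trend removed, below the central 95% both ways) and ribosomal protein genes higher in 72 of 78 (0.32, above it, but 0.18 with the trend removed, inside it). Markers of other classes differed in the same cells. Dividing cell markers were higher in 15 of 15 members on day 6 (0.36, and 0.62 with the trend removed), although G2/M genes, at 0.19 over the class, were -0.03 in cluster 3 alone. Epithelial markers were higher in 3 of 3 on day 3 (1.10).

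The P-G3 differences of the 2 days were more alike across genes than either was like differentiation. The Pearson correlation across 6029 genes between the log2 ratios of P-G3 on day 3 and on day 6 was 0.85 (Spearman 0.87), and 0.77 for both with the length trend removed. For P-G3 on day 3 against the differentiation difference of day 6 and day 0, the correlations over 6244 genes were 0.19 and 0.06, and 0.26 and 0.16 with the trend removed. For P-G3 on day 6 against day 3 and day 0 they were -0.00 and -0.09 over 6264 genes, and 0.05 and -0.00 with the trend removed. Neither pair shares a library, and genes are not independent replicates. Whether the effect of P-G3 differed between day 3 and day 6 was not tested.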

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

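In this part, the tests of small intact cells and of cytoplasm without nuclei were chosen only after the result was seen, and the test of free RNA was chosen before it.

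The G2/M genes had medians of opposite sign on the 2 days of P-G3 treatment, -0.0463 on day 6 and 0.0223 on day 3, a difference between groups that was not tested. On day 6 the list had 16 members higher and 21 lower, and its median was 0.28 under TMM scaling and 0.32 under median-of-ratios scaling. Barcodes that the cell filter left out, and that only the alternative with all deposited barcodes uses, carried adipocyte RNA on day 6. Fabp4 stood at 17990 CPM in 2814 left-out barcodes untreated and 15783 CPM in 2173 with P-G3, against 27.5 CPM in 37 left-out barcodes on day 0. The nuclear RNA Malat1 stood at 10800 and 10641 CPM in the left-out barcodes of day 6. In cells of these libraries with at least 10000 UMIs it stood at 4690 and 3516 CPM.

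Among the kept cells of day 6, cluster 0 held 838 barcodes untreated and 1564 with P-G3, with medians of only 1765.5 and 1838.5 UMIs, Fabp4 at 41536 and 33661 CPM, and Malat1, an RNA held in the nucleus, at 216 and 283 CPM. Free RNA from all cells of the library would carry matrix transcripts, yet the matrix list lay at median log2 ratios of -2.82 and -2.17 against cells with at least 10000 UMIs. The barcodes of this cluster therefore did not carry the RNA mix of the larger cells. The cluster was itself formed on expression, with 9 adipocyte markers leading in it, and other low-UMI barcodes fell into clusters that were not tested. The values thus cannot decide on free RNA for all low-UMI barcodes of day 6. Small intact adipocyte-like cells would carry Malat1 at the level of the adipocyte-like cells, yet its log2 ratio to them was -4.42 untreated and -3.55 with P-G3. Part of this goes with length, as the Spearman correlation of these ratios with transcript length was -0.64 and -0.49. With the length trend removed, the list of 3 nuclear RNAs lay at -2.15 (-3.07 to -2.10) and -1.87 (-2.74 to -0.89). It thus stayed lower than in the adipocyte-like cells, by less than Malat1 as measured. Low-UMI cluster 12, with 80 untreated and 66 P-G3 barcodes of day 6, was unlike cluster 0, with Malat1 at 180720 CPM. Cytoplasm of adipocyte-like cells without nuclei should raise the adipocyte identity list. The list lay at -0.28 (interval -0.71 to 0.25) and -0.47 (-0.90 to -0.03) against the larger cells, where the median of all genes was itself -0.74 and -0.33. Against the adipocyte-like cells it lay at -0.70 (-1.07 to -0.05) and -0.62 (-1.10 to -0.23), where the median of all genes was -0.71 and -0.34. With the length trend removed it was 0.19 (-0.04 to 0.36) and -0.26 (-0.62 to 0.19) against the larger cells. Against the adipocyte-like cells it was then -0.24 (-0.40 to 0.10) and -0.36 (-0.80 to 0.03). These values do not decide on cytoplasm without nuclei, which cannot be told apart from other sources. RNA set free by adipocytes alone, and any effect of P-G3 on how cells break or survive dissociation, stay open as untested.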

How the results depend on the processing

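Added after seeing the data were removal of the length trend, a minimum of 10000 UMIs per cell, leaving out the 5% of cells with most UMIs, the naming threshold, and each adipocyte-like cluster alone. No paired analysis by replicate was possible because each group has 1 library, and a fit of P-G3 with day as the block, which would leave 1 residual degree of freedom, was not made. Depth limits genes with few counts, not the counts at 20 CPM, since 3 counts are at most 0.0339 CPM. Of 211 list medians, 211 kept their value within the interval with all deposited barcodes, 211 with at least 10000 UMIs per cell and 211 without doublet calls, against 151 under TMM scaling, 137 under median-of-ratios scaling and 160 with the length trend removed. The settings that kept all 211 could hardly move a sum. Kept barcodes held at least 95.5% of each library's UMIs, cells under 10000 UMIs at most 4.05% of the kept UMIs, and doublet calls were very few. They therefore say little on doublets or on the cell filter. The matrix list on P-G3 ranged from -0.76 to -0.46 on day 3 and from -1.12 to -0.41 on day 6, and fatty acid synthesis from -0.16 to 0.18 and from -0.34 to 0.08. Except where the construction shows it, as with other minimums and folds, the cause of the moves below was not tested.

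Counts follow as higher and lower for day 3 on day 0, day 6 on day 3, day 6 on day 0, P-G3 on day 3 and P-G3 on day 6. With at least 100 CPM they were 87 and 91, 178 and 71, 320 and 205, 2 and 27, and 3 and 39. With no minimum they were 766 and 474, 797 and 691, 1870 and 1279, 12 and 240, and 11 and 422. At 1.5-fold they were 759 and 571, 1017 and 659, 1732 and 1163, 64 and 701, and 102 and 1339. At 3-fold they were 172 and 82, 187 and 141, 518 and 336, 1 and 10, and 1 and 12. With 100 CPM the Spearman correlation of P-G3 on day 3 with differentiation to day 6 was 0.189, and that of P-G3 on day 6 with differentiation to day 3 was 0.0712. The tolerance of 0.1 for correlations was chosen after their main values were seen.

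With a pseudocount of 5 CPM the adipocyte identity median was 3.01 for day 3 and 5.31 for day 6 on day 0, and 68 and 85 genes were lower with P-G3 on days 3 and 6. Giving each cell the same weight left 3 genes higher with P-G3 on day 6.

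TMM scaling gave 26 higher and 41 lower genes with P-G3 on day 3, and 56 and 37 on day 6. It moved adipocyte identity on day 3 to 0.61, fatty acid synthesis to 0.11 and 0.028, triglyceride synthesis on day 3 to 0.20 (reversed), matrix genes to -0.49 and -0.66, and G2/M genes on day 6 to 0.28 (reversed). Within adipocyte-like cells it gave 0.23 for identity on day 3, and -0.050 for fatty acid synthesis and -0.14 for matrix genes on day 6. Median-of-ratios scaling gave 27 and 35, and 81 and 32 genes. It moved identity to 0.64 and 0.27, fatty acid synthesis to 0.14 and 0.078 and matrix genes to -0.46 and -0.64. It reversed triglyceride synthesis on day 3 (0.22) and, on day 6, fatty acid uptake (0.022), mitochondrially encoded transcripts (0.013) and G2/M genes (0.32).

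With the length trend removed, 30 genes were lower on day 3, and 26 were higher and 28 lower on day 6 with P-G3. Fatty acid synthesis moved to 0.18 and 0.077 and matrix genes on day 6 to -0.41. Reversed were triglyceride synthesis (0.27) and insulin signalling (0.031) on day 3, and insulin signalling (0.031), fatty acid uptake (0.065), G2/M genes (0.26) and glucocorticoid targets (0.011) on day 6. The Spearman correlation between the P-G3 differences of the 2 days was 0.766. Within adipocyte-like cells fatty acid synthesis moved to 0.0062 on day 6, and reversed were fatty acid synthesis (0.0034) and insulin signalling (0.00058) on day 3, matrix genes on both days (0.015 and 0.019) and epithelial markers on day 6 (-0.017).

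The triglyceride synthesis median on day 3 reversed to 0.028 without the 5% of cells with most UMIs and to 0.0091 for members with at least 20 CPM. With at least 1000 genes and at most 10% mitochondrial UMIs, the G2/M median on day 3 reversed to -0.0069, matrix genes on day 6 moved to -1.12, and adipocyte-like cells made up 11.3%, 13.2%, 46.9% and 54.3% of cells on day 3 and day 6, each without and with P-G3.

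Shares of adipocyte-like cells moved with the clustering. At 0.5 times the resolution they were 0.250% and 0.128% on day 3. Without the doublet calls they were 8.24% and 12.2% on day 3, and 37.8% and 36.3% on day 6. With all variable genes they were 7.79% on day 3 untreated and 39.5% on day 6 with P-G3. With cells thinned first they were 2.09%, 2.78%, 43.3% and 42.9%, and with at least 10000 UMIs per cell 12.7%, 19.1%, 64.0% and 79.1%. With all variable genes fatty acid synthesis within these cells was -0.33 on day 3, and ATF4 targets on day 3 (-0.0027), S phase (-0.12) and G2/M genes (-0.053) on day 6 reversed. In cells with at least 2 Adipoq UMIs identity was -0.16 on day 3 and matrix genes -0.62 on day 6, and S phase (-0.37) and G2/M genes (-0.055) on day 6 reversed. In cluster 3 alone S phase (-0.12) and G2/M genes (-0.035) on day 6 reversed, and in cluster 10 alone S phase reversed (-0.064) and matrix genes moved to -0.72. Epithelial markers gave no value in cluster 10, where no member reached 5 CPM. List members are chosen anew after each scaling.

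Dividing cells, from day 0 to day 6 with P-G3, were 86.5%, 78.6%, 83.5%, 41.2% and 35.0% without thinning. Thinned to the 25th percentile they were 27.4%, 26.6%, 30.1%, 3.42% and 3.03%, and with 1 more UMI required 10.1%, 14.6%, 15.3%, 0.757% and 1.24%. With at least 10000 UMIs per cell they were 3.11% and 2.98% on day 6.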

Other observations

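Lists not described above are given here for the differentiation comparisons, and some of them lay inside the central 95% of random lists. Adipogenic transcription factors were higher in 15 of 17 members on day 3 against day 0 (1.63), led by Nr1h3 (3.71), and in 17 of 19 on day 6 against day 3 (0.47). Over the same steps beta-oxidation genes were higher in 19 of 20 and 20 of 21 members (0.60 and 0.61) and lipid droplet genes in 12 of 15 and 12 of 16 (0.55 and 0.79). Against day 0, adipokines were higher in 8 of 12 members on day 3 (1.36) and 10 of 13 on day 6 (3.28). Interferon response genes were lower in 10 of 12 members on day 3 (-0.66), with Ifi27l2a at -3.55, and higher in 9 of 10 from day 3 to day 6 (0.29, inside the central 95%). Mitochondrially encoded transcripts were higher in 13 of 13 on day 3 (0.97). In NRF2 targets the antioxidant gene Gpx1 stood at -2.04 on day 6 against day 0 and Sod1 at 2.11, with 16 of 25 members higher (0.60). Heat shock genes, p53 targets, lysosome genes and autophagy genes had medians of -0.29, 0.38, -0.30 and 0.44 over the same interval, and only lysosome genes lay outside the central 95%.

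With P-G3, basement membrane genes were lower in 13 of 15 members on day 3 (-0.54) and 15 of 16 on day 6 (-0.74), with Hspg2 at -0.80 and -1.22, and stayed below the central 95% at -0.13 and -0.14 with the length trend removed. Cell cycle inhibitors and quiescence genes were lower in 15 of 17 members on both days (-0.46 and -0.56), and lay inside the central 95% with the trend removed. Adipokines were higher in 9 of 12 on day 3 (0.35, percentile 100) and split 7 and 6 on day 6 (0.03). ATF4 targets were higher in 15 of 25 on day 3 (0.10) and lower in 20 of 28 on day 6 (-0.18, but 0.16 under TMM scaling), a difference between days that was not tested. NRF2 targets were lower in 16 of 25 on day 6 (-0.27, but 0.05 under TMM scaling, and -0.19 with the trend removed, below the central 95%). Glucocorticoid targets were lower in 15 of 20 on day 6 (-0.44), but 0.01 with the trend removed. Interferon, heat shock, p53 and autophagy lists lay inside the central 95% on both days as measured. Ribosomal protein genes were higher in 74 of 78 members on day 3 (0.13) and 68 of 78 on day 6 (0.22), and had medians of 0.04 and 0.08 with the trend removed. The nuclear RNAs Malat1 and Neat1 stood at -0.52 and -0.80 on day 3 and at -0.47 and -1.24 on day 6, and Malat1 at 0.18 on day 6 with the trend removed.

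Markers of macrophages, endothelial cells, lymphocytes, erythroid cells and skeletal muscle had at most 2 members with 5 CPM in any comparison, and so gave no median. Epithelial markers had 4 members on day 6 with P-G3, all higher (0.30). Chondrocyte and osteoblast markers were lower in 3 of 3 members on day 3 (-1.28), which rests on Spp1 and Sox9.

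Of the tests that follow, the split of the cell class test into clusters with many and few UMIs and those of library preparation, of the length trend as the whole cause, and of the length trend with the cell mix were chosen only after the result was seen.

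The ratio of P-G3 to untreated was lower for longer transcripts on both days. A difference in UMIs per cell between the libraries is argued against, because among cells with 30000 to 60000 UMIs the Spearman correlation across genes was -0.612 on day 3 and -0.594 on day 6. A different mix of cell classes is argued against outside the low-UMI clusters, where the value nearest 0 over 6 classes and days was -0.565, but over all 8 it was -0.108, in the low-UMI clusters of day 3 (-0.357 on day 6), so for these clusters it cannot be told apart. Library preparation or RNA quality could give such a trend and cannot be told apart from an effect of P-G3 on long transcripts, because there is 1 library per group. That effect stays open as untested.

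Matrix genes were lower with P-G3 on both days. The length trend as the whole cause is argued against by the percentile of the list median after its removal, which was 0 on day 3 and 0 on day 6 among random lists. Fewer preadipocyte-like cells as the whole cause cannot be told apart, since the list median nearest 0 over 8 classes and days was -0.28, between the bounds set for it. The length trend and the mix of cells together could account for much of the pattern and cannot be told apart from it either, as 4 of 9 clusters and days kept a median below the central 95% with the trend removed, cluster 5 on day 3 (-0.38) and clusters 10, 8 and the low-UMI cluster 0 on day 6 (-0.14, -0.10 and -0.57). Lower matrix expression in cells exposed to P-G3 stays open as untested.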
